A study of Homo sapiens with 5 samples.

How the data were processed

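Poly-A-selected RNA was sequenced from cells of a derivative of the human colorectal carcinoma line HCT116, in 3 control libraries and 2 libraries of cells with an ORC1 deletion made by CRISPR/Cas9. Per the labels' protocols, the libraries were made with a directional kit and sequenced from both ends. Control and deletion cells were grouped by the titles of the samples, which also number the replicates. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these 5 libraries, which may be technical. They also do not say whether the deletion libraries came from 1 clone or several.

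Per the submitters' processing notes, the tools were FastQC 0.11.5, HISAT2 2.2.1, SAMtools 1.12, HTSeq 2.0.5 and DESeq2 1.42.0, with the hg38 build of the human genome. The gene annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap another gene, antisense genes and near-identical gene copies are treated as uncertain. The deposited table holds raw read counts per gene symbol and library, as whole numbers whose totals differ between libraries. Per the file headers, the same table holds the authors' DESeq2 comparison of deletion with control: a mean of normalised read counts per gene (a signal over all libraries), the log2 fold change with its standard error, the Wald statistic (a score), and p-values with their adjusted values. A repeat of that comparison with DESeq2 1.42.0 gave log2 fold changes within 1.65e-10 of those the authors deposited. It did so only when the 2 HTSeq summary entries, reads assigned to no gene and reads in more than 1 gene, were kept as if they were genes.

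These summary entries were left out of library sizes and tests here. Reads assigned to no gene were 3.35%, 3.85% and 3.69% of the counts in control replicates 1 to 3, and 4.72% and 4.63% in deletion replicates 1 and 2. Reads in more than 1 gene were 6.31%, 6.34% and 6.35%, and 6.42% and 6.42%. All per-sample columns were used, and 0 were left aside.

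Counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15) and no covariate. The filter kept 14492 of the 54651 genes in the table, of which 27674 had any count. Adjusted p-values are Benjamini-Hochberg values over these 14492 genes, with a threshold of 0.05. Standard errors are those of the quasi-likelihood test, the log2 fold change divided by the square root of F. Normalised read counts are counts divided by the TMM-scaled library size and multiplied by the mean of these sizes. Gene positions came from NCBI RefSeq on GRCh38, matched by symbol or by an older symbol that points to a single gene. Of the table's genes, 51587 (94.4%) matched, and of the tested genes 14219 (98.1%).

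Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and again with the correlation estimated from the libraries. fry was run as a test of each list by itself. fry's p-value asks whether the genes of a list move, on balance, in one direction, and its mixed p-value whether they change in either direction. Of 37 lists, the 32 with at least 5 tested members were tested and adjusted together. The lists covered the ORC subunits, the cell cycle and DNA replication, chromatin, immune signalling, intestinal identity, metabolism, stress, translation, mitochondria, and markers of other cell types. The design, the alternatives, the lists and the rule for named genes were set before the data were examined. The rule names ORC1 and the other ORC subunits. It adds the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the test with a mean normalised count of at least 100. For each list it adds up to 4 members, the 2 with the smallest p that rose and the 2 that fell. Members named beyond these were chosen after their values were seen. Some genes that the rule takes, and 1 of the lists, are not reported here.

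Neighbouring genes were scanned along each chromosome with the median log2 fold change of 41 consecutive tested genes. A window passed when its median exceeded the largest one found in 95% of 1000 shuffles of the gene order, and a block needed at least 20 genes in a row at the centre of a passing window. This scan was chosen after the data were seen.

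The scripts' tests were tried on simulated data with 200 changed genes among the 14492 tested genes, for the comparison of deletion with control at the real depths. They recovered 52% of genes changed 1.25-fold, 70% at 1.5-fold, 92% at 2-fold and 94% at 4-fold, with 19 false calls among 173. Fold changes of under 1.5 were therefore missed more often than larger ones in that simulation. The share of false calls in it was above the nominal level. The real comparison called 53.2% of the tested genes, far more than were changed in the simulation. The recovered and false shares therefore need not hold for the real comparison. Intervals on ratios of few counts are exact Poisson intervals at 95% and cover counting error only, as the reads are not independent molecules.

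Alternatives tried were another scaling, DESeq2 in place of edgeR, other filters on low counts, other thresholds, a Benjamini-Yekutieli adjustment, a replicate block, leaving out each library in turn, genes with a symbol only, and other rankings and correlations for the lists. The replicate block used only the replicate numbers that both groups hold, so it left out control replicate 3. Plain library totals, and the tests without the genes of 2 blocks on chromosome 5, were added after the data were seen. Other assays and cell lines of the study were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.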

Results

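RNA levels were compared between HCT116-derived cells with an ORC1 deletion and control cells of the same line, wild-type for ORC1. The sample titles give both groups a shared genotype at another gene, which is not reported here. Neither group is therefore unmodified HCT116. ORC1 encodes the largest subunit of the origin recognition complex (ORC), which marks the sites where DNA replication starts and loads the MCM helicase. The series as a whole asks how ORC2 shapes the epigenome and chromosome structure. This comparison asks which RNAs differ between cells with a deletion of another ORC subunit and control cells. Effects of the deletion cannot be told apart here from other differences between these cells, such as those that arise when a clone is derived. Reads assigned to genes numbered 19421595, 18277240 and 16074763 in control replicates 1 to 3 and 15095195 and 13568189 in deletion replicates 1 and 2. The groups separated on the first principal component, which held 72% of the variance, while the second held 10.2%. Pairs of replicates differed by more than counting noise, with a chi-square per degree of freedom between 2.05 for the deletion pair and 3.25 for control replicates 1 and 3. The biological coefficient of variation was 3.66%.

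ORC1 RNA was higher, not lower, in the libraries labelled ORC1 deletion. ORC1 (chromosome 1, 52372829 to 52409503, GRCh38) had 277, 288 and 264 reads in control replicates 1 to 3 and 558 and 430 in deletion replicates 1 and 2. Its normalised count was 259 ± 19.1 (SD, n = 3) in control and 550 ± 61.5 (SD, n = 2) in deletion libraries, a 2.13-fold rise. The edgeR quasi-likelihood test gave a log2 fold change of 1.09 (SE 0.0948, Benjamini-Hochberg adjusted p = 4.24e-12). Counts per gene do not show whether the edited transcript codes for protein, so the level does not check the genotype in the label. In the annotation ORC1 overlaps PRPF38A at its end, and reads in the overlap cannot be assigned without the strand setting. In the authors' deposited table the log2 fold change of ORC1 was 1.08 (SE 0.115, adjusted p = 9.39e-20).

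Among the other ORC subunits, ORC2, ORC3 and ORC6 also rose. ORC6, the smallest subunit, went from 569 ± 25.7 to 882 ± 94.5 normalised counts, ORC3 from 474 ± 35.7 to 692 ± 39.7 and ORC2 from 666 ± 16.03 to 791 ± 2.53 (SD, n = 3 and 2). Their log2 fold changes were 0.63 (SE 0.0723, adjusted p = 3.13e-09), 0.54 (SE 0.0779, adjusted p = 3.37e-07) and 0.25 (SE 0.0662, adjusted p = 0.00172) in the edgeR test. ORC4 at 0.16 (edgeR adjusted p = 0.0555), ORC5 at 0.12 (0.306) and LRWD1, an ORC-associated protein, at -0.09 (0.282) did not pass. ORC4 passed without control replicate 2 (edgeR adjusted p = 0.0249), at a mean normalised count of at least 10 (0.0487) or 100 (0.0238), among genes with a symbol only (0.0496) and with plain library totals (0.00873). Of the 7 genes of this list 4 rose over all genes tested and 5 when adjusted over the list alone. Camera did not call the list (adjusted p = 0.0843, and adjusted p = 0.24 with an estimated correlation), but did so with no filter on low counts (adjusted p = 0.00505) and with ranks of the statistic (0.0288).

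**Figure D1:**
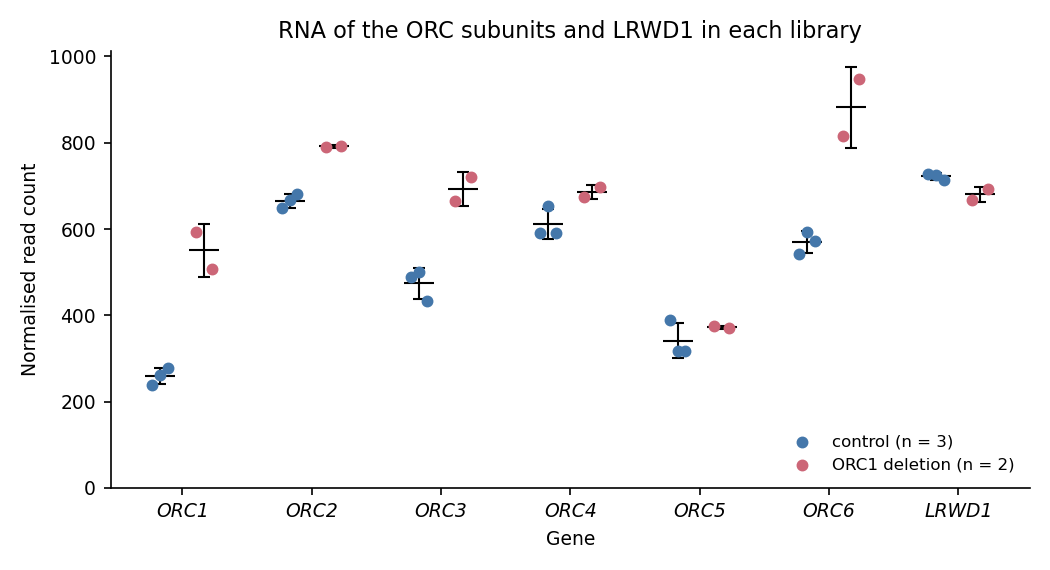
Normalised read counts (y axis) of the ORC subunits and LRWD1 (x axis) in each library, with control libraries in blue and ORC1 deletion libraries in red; long bars are group means and whiskers are SD (n = 3 and 2). ORC1 lies at 259 in control and 550 in deletion libraries on average, and its groups do not overlap.

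The largest rises were in ALPP and ALPG, neighbouring genes for placental-type alkaline phosphatases on chromosome 2 (232378751 to 232382889 and 232406844 to 232410714). ALPP had 11 reads over the 3 control libraries and 4292 over the 2 deletion libraries, a ratio scaled to library totals of 732 (95% interval 409 to 1467). ALPG had 6 and 2246, a ratio of 702 (322 to 1916). The sequences of these genes are so alike that reads may be split between them, so their separate levels are uncertain. SEMA3A, a secreted guidance factor, rose from 82.5 ± 18.1 to 2044 ± 4.35 normalised counts (24.6-fold, log2 4.62, SE 0.0861). SUSD2 rose from 165 ± 7.57 to 2927 ± 42.7 (17.7-fold, log2 4.14, SE 0.0608) and LOXL4, a lysyl oxidase of the extracellular matrix, from 39.0 ± 5.84 to 1073 ± 27.6 (27.3-fold, log2 4.77, SE 0.109). CCL26, a chemokine gene (log2 4.68), also rose, and the scaffold gene IQGAP2 (3.53), the transcription factor gene GLIS3 (3.16) and the transporter gene SLC16A6 (3.13) rose by less. EIF3CL, at log2 3.35, rested on deletion replicate 2, with 643 reads against 47 in replicate 1. Without that library it did not pass the edgeR test (log2 0.34, adjusted p = 0.492), and it is a near copy of EIF3C.

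Among the largest falls, PDE4B, a cAMP phosphodiesterase, went from 1135 ± 17.8 to 14.2 ± 4.98 normalised counts (80.5-fold lower, log2 -6.33, SE 0.139). MAL2, a protein of apical transport, went from 2455 ± 27.1 to 95.9 ± 8.90 (25.5-fold lower, log2 -4.67, SE 0.0753). RNF43, an E3 ligase that removes Wnt receptors, went from 1716 ± 30.5 to 74.4 ± 13.6 (22.9-fold lower, log2 -4.52, SE 0.0898), and S100A14 from 3898 ± 85.2 to 172 ± 27.4 (22.8-fold lower, log2 -4.51, SE 0.0644). PCDH7, a protocadherin (log2 -3.99), DSC3, a desmosomal cadherin (-3.69), LEMD1 (-3.53) and the transcription factor gene NFIA (-3.16) fell too. SH3BGRL was lower at log2 -6.07, with 2 and 13 reads in the deletion libraries, and its log2 fold change was -5.21 without deletion replicate 1 and -7.99 without deletion replicate 2. The edgeR test with Benjamini-Hochberg adjustment gave adjusted p-values from 4.55e-35 (ALPP) to 1.51e-07 (EIF3CL) for the named genes with the largest rises and falls.

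Over all genes, 3777 rose and 3929 fell in the edgeR test, 53.2% of the 14492 tested. A change of at least 2-fold was found for 614 genes that rose and 485 that fell. At a mean normalised count of at least 100, which leaves fewer genes to test, these counts were 196 and 225, with the Benjamini-Yekutieli adjustment 398 and 400, and without deletion replicate 1 they were 456 and 489. Groups did not overlap for 9758 tested genes (67.3%), where chance gives 20% for 3 libraries against 2. Protein-coding genes made up 12489 of the tested genes, with 3467 higher and 3656 lower. Long non-coding RNA genes numbered 894, with 151 higher and 119 lower. The balance depends on the scaling: with plain library totals, chosen after seeing the data, 4539 genes were higher and 3263 lower, so that 58.2% of the calls were higher in place of 49%. The authors' deposited table called 3141 genes higher and 3656 lower, of which 3103 and 3641 were also called here.

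Genes of mitosis and DNA replication rose together. All 30 tested mitosis genes rose, with a median log2 fold change of 0.67, among them the mitotic kinase gene PLK1 (1873 ± 61.1 to 3660 ± 96.4 normalised counts, log2 0.97, SE 0.0386) and the cytokinesis gene ANLN (log2 0.85, SE 0.0322). All 23 origin licensing and firing factors rose, with a median of 0.57, among them the helicase subunits MCM4 (2857 ± 16.8 to 5415 ± 45.1, log2 0.92, SE 0.0324) and MCM5 (log2 0.87, SE 0.0403). Of 30 genes of the replication fork and nucleotide supply 28 rose, with a median of 0.50, and RPA2 and TIPIN did not pass. The nucleotide synthesis genes TK1 (log2 1.17, SE 0.0385) and RRM2 (log2 1.04, SE 0.0339) led this list. Adjusted over the list alone, 30, 23 and 28 genes rose. Camera called the lists at adjusted p = 3.48e-31, 6.16e-14 and 1.62e-12. These were the 3 of its 17 called lists that held with an estimated correlation, each at adjusted p = 0.0384.

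Other lists tied to division and the genome moved in the same direction. Of 31 DNA damage checkpoint and repair genes 22 rose and 2 fell, over all genes and adjusted over the list alone (median 0.46, camera adjusted p = 4.16e-05, but adjusted p = 0.0719 with an estimated correlation). FANCD2 (log2 1.00, SE 0.0786) and the mismatch repair gene MSH6 (0.79, SE 0.0444) rose, and RAD17 (-0.87, SE 0.08) and the helicase gene WRN (-0.52, SE 0.0778) fell. Of 25 cohesin, condensin and CTCF genes 15 rose and 2 fell on both counts, all genes and adjusted over the list alone (median 0.16, camera adjusted p = 0.000149, but adjusted p = 0.109 with an estimated correlation). ESCO2, an acetyltransferase for cohesin, rose (log2 1.13, SE 0.0712), as did the condensin II gene NCAPG2 (0.85, SE 0.0482). STAG1 (-0.18) and ESCO1 (-0.19) fell, but STAG1 did not pass without control replicate 3 (edgeR adjusted p = 0.0922) or deletion replicate 1 (0.29). ESCO1 did not pass without control replicate 1 (0.0995), deletion replicate 1 (0.0893) or deletion replicate 2 (0.109), and with plain library totals neither passed (0.13 and 0.144). Of 17 centriole duplication genes 13 rose and CEP120 (log2 -0.32, SE 0.0714) fell, again also when adjusted over the list alone (median 0.40, camera adjusted p = 0.0101, but adjusted p = 0.196 with an estimated correlation). PLK4, the kinase that starts centriole duplication, rose by log2 0.62 (SE 0.0698) and STIL by 0.74 (SE 0.0484).

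In the list of cyclins, CDKs and CDK inhibitors, which also holds E2F and other regulators, 19 of 32 tested members rose and 5 fell, and 20 and 5 when adjusted over the list alone (median 0.33, camera adjusted p = 0.000955, but adjusted p = 0.196 with an estimated correlation). CCND3 rose from 553 to 1266 mean normalised counts (log2 1.19, SE 0.0634) and CCND1 from 14334 to 23119 (0.69, SE 0.0268). The members that fell were CDKN1A, which encodes the CDK inhibitor p21 (2986 ± 110 to 1797 ± 78.3, log2 -0.73, SE 0.0422), CDK6 (-0.48, SE 0.0468), CDKN1C, CDKN2A and RBL2. Within this list, which holds part of these genes, 6 of 11 cyclin and CDK genes rose and 1 fell. Among the 26 tested protein-coding genes with the symbol stem CDK, in the list or not, 8 rose and 9 fell. Of 7 CDK inhibitor genes 3 fell and 2 rose, CDKN2D (0.74, SE 0.101) and CDKN2C (0.52, SE 0.132), but CDKN2C did not pass without deletion replicate 1 (edgeR adjusted p = 0.105).

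All 40 members of the list of cytosolic ribosomal proteins, which holds part of these genes, fell, over all genes and adjusted over the list alone, with a median log2 fold change of -0.58. RPL3 went from 48570 ± 1106 to 25706 ± 77.8 normalised counts (log2 -0.92, SE 0.0254) and RPL13 from 43153 ± 809 to 25006 ± 136 (log2 -0.79, SE 0.0252). Camera gave adjusted p = 2.21e-51 for the list, but adjusted p = 0.109 with an estimated correlation, which was 0.55 for this list. Of 14 heat shock chaperone genes 12 rose, 13 when adjusted over the list alone, and HSPA1A and HSPE1 did not pass over all genes (median 0.46, camera adjusted p = 1.11e-10, but adjusted p = 0.0719 with an estimated correlation). HSPA8, the constitutive HSP70, rose from 20518 to 36011 mean normalised counts (log2 0.81, SE 0.0245) and HSP90AA1 from 49873 to 72906 (0.55, SE 0.0231). Of 27 genes of the unfolded protein and integrated stress responses 17 fell and 7 rose on both counts, all genes and adjusted over the list alone (median -0.36, camera adjusted p = 7.63e-05, but adjusted p = 0.109 with an estimated correlation). TRIB3, a target of the integrated stress response, fell 5.09-fold, from 3835 ± 102 to 754 ± 4.89 (log2 -2.35, SE 0.0458), and the amino acid transporter gene SLC3A2 fell too (-0.83, SE 0.0302). The chaperone genes of the endoplasmic reticulum CALR (log2 0.83, SE 0.0274) and PDIA4 (0.64, SE 0.0293) rose.

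Of 25 interferon-stimulated genes 16 rose, 0 fell and 9 did not pass, with the same count adjusted over the list alone, and the median log2 fold change was 0.75. IFIT1 rose from 62.1 ± 11.8 to 385 ± 14.2 normalised counts (log2 2.62, SE 0.142) and OAS3 from 534 ± 21.5 to 1594 ± 66.1 (1.57, SE 0.0593). Camera gave adjusted p = 2.35e-06, but adjusted p = 0.0719 with an estimated correlation. Of 28 immediate early genes, which answer growth factor signals within minutes to hours, 18 fell and 6 rose on both counts, all genes and adjusted over the list alone. Their median was -0.29 (camera adjusted p = 2.69e-08, but adjusted p = 0.0719 with an estimated correlation). MYC fell from 7611 ± 179 to 3372 ± 97.8 (log2 -1.17, SE 0.0332) and SPRY4, a feedback inhibitor of ERK signalling, from 3891 ± 61.6 to 1453 ± 25.7 (-1.42, SE 0.0397), whereas FOSL2 (0.85, SE 0.0506) and KLF6 (0.35, SE 0.0299) rose.

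Of 27 genes of epithelial junctions and keratins 17 fell and 6 rose, with the same counts adjusted over the list alone (median -0.28, camera adjusted p = 0.0321, but adjusted p = 0.239 with an estimated correlation). This list also did not pass at a mean normalised count of at least 100 (adjusted p = 0.0574), with plain library totals (0.0779) or when ranked by log2 fold change (0.263), and over its alternatives the adjusted p ranged from 4.64e-05 to 0.263. Tight junction genes CLDN4 (5750 ± 180 to 2845 ± 63.6 normalised counts, log2 -1.02, SE 0.035) and CLDN7 (-0.99, SE 0.0375) fell. The keratin pair KRT8 (41188 ± 641 to 76058 ± 320, log2 0.88, SE 0.0231) and KRT18 (0.84, SE 0.025) rose. Of 22 mesenchymal and extracellular matrix genes 10 rose and 4 fell on both counts, all genes and adjusted over the list alone (median 0.21, camera adjusted p = 0.0249, but adjusted p = 0.29 with an estimated correlation). THBS1, a secreted matrix glycoprotein, rose 8.46-fold from 576 ± 23.2 to 4880 ± 92.7 (log2 3.08, SE 0.0434) and CCN1 by log2 1.11 (SE 0.0812). SERPINE2 (-0.46, SE 0.0316), LAMB3 and MMP1 were among those that fell. The log2 fold change of MMP1 was -7.92 without deletion replicate 1 and -1.79 without deletion replicate 2, so its size is uncertain. This list also did not pass without control replicate 3 (adjusted p = 0.0503), with no filter on low counts (0.167), with ranks of the statistic (0.169) or when ranked by log2 fold change (0.522), and the smallest adjusted p over its alternatives was 0.00982. Its median was 0.009 without deletion replicate 2 (adjusted p = 0.0468).

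**Figure D2:**
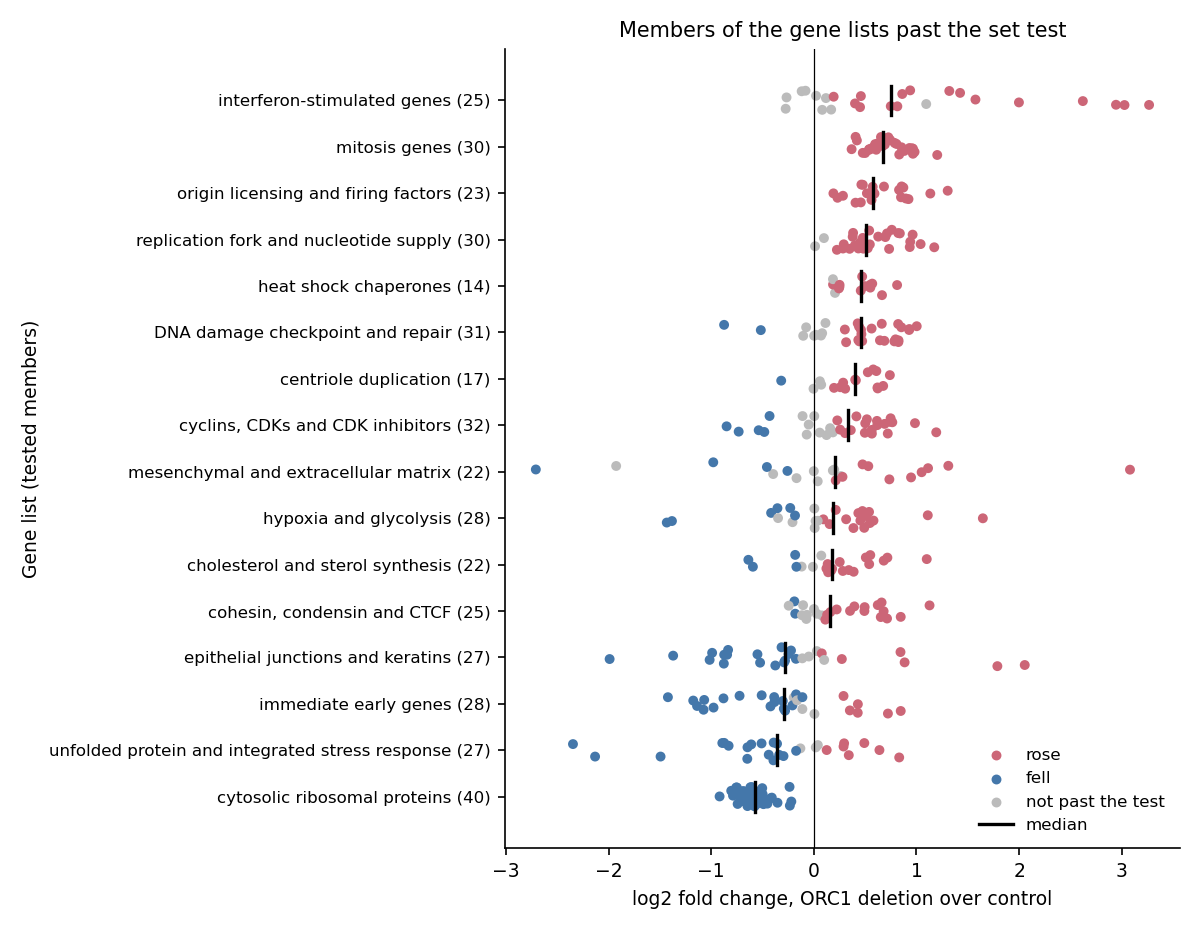
Log2 fold change of deletion over control (x axis) for each tested member of 16 of the 17 gene lists called by camera with the preset correlation (y axis, number of tested members in brackets); red members rose, blue fell, grey did not pass the edgeR test and black bars are medians. Every ribosomal protein gene of the list lies below 0 and every mitosis gene above 0.

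Of 22 cholesterol and sterol synthesis genes 15 rose and 4 fell on both counts, all genes and adjusted over the list alone (median 0.17, camera adjusted p = 0.0039, but adjusted p = 0.115 with an estimated correlation). HMGCS1 rose from 1400 to 3001 mean normalised counts (log2 1.1, SE 0.0412), while SREBF2, the transcription factor of this pathway (-0.59, SE 0.0374), SQLE (-0.64, SE 0.0686), CYP51A1 and MSMO1 fell. Of 28 hypoxia and glycolysis genes 16 rose and 6 fell, with the same counts adjusted over the list alone (median 0.18, camera adjusted p = 0.013, but adjusted p = 0.268 with an estimated correlation). The glucose transporter gene SLC2A3 (log2 1.65, SE 0.0646) and PKM (0.50, SE 0.0237) rose, and NDRG1 (9658 to 3704, log2 -1.38, SE 0.0325) and hexokinase 2, HK2 (-1.43, SE 0.0557), fell.

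The remaining 14 tested lists were not called by camera in the reported comparison. Of these, 4 were called with no filter on low counts: antigen presentation (adjusted p = 0.00875), ribosome biogenesis (0.000882), fatty acid synthesis (0.0292) and mitochondrially encoded transcripts (0.0373). Antigen presentation was also called at a mean normalised count of at least 100 (0.0479), and it (0.0288) and ribosome biogenesis (0.0257) with ranks of the statistic. Wnt target and crypt stem genes split, with 6 higher and 5 lower of 15 (8 and 5 adjusted over the list alone). The negative feedback gene AXIN2 (log2 1.14, SE 0.0815) rose, while RNF43 and MYC fell. The median of this list was 0.25, its mean -0.18 and its test pointed down (adjusted p = 0.0597). Of 16 antigen presentation genes 8 rose, 9 adjusted over the list alone, among them HLA-C (0.49, SE 0.0308) and B2M (0.45, SE 0.0479), and TAP1 and NLRC5 fell (camera adjusted p = 0.0597). Neither fall passed the edgeR test without deletion replicate 2 (adjusted p = 0.181 and 0.071), nor TAP1 with plain library totals (0.0972). Of 37 Polycomb and heterochromatin factors 17 rose and 12 fell (18 and 13 adjusted over the list alone, camera adjusted p = 0.187), with the heterochromatin protein genes CBX5 (0.63, SE 0.0414) and CBX1 (0.47, SE 0.0344) higher and JARID2 (-0.57, SE 0.0446) lower. Of 27 HOX genes 7 rose and 5 fell, with HOXB7 higher (0.49, SE 0.0638) and HOXB9 lower (-0.96, SE 0.0588, camera adjusted p = 0.935). Of 28 ribosome biogenesis genes 14 fell and 4 rose, with RRP12 at -0.59 (SE 0.0475) and NOP58 at 0.33 (SE 0.0461, camera adjusted p = 0.127). Of 6 metallothionein and zinc genes 4 rose, led by MT1E (0.92, SE 0.0421) and MT1X (1.00, SE 0.106), and SLC30A1 fell (-0.57, SE 0.0878, camera adjusted p = 0.0877). Of 12 replication-dependent histone genes 5 rose and 0 fell, among them H2BC12 (0.47, SE 0.0749) and H1-2 (0.42, SE 0.093, camera adjusted p = 0.272), though poly-A selection captures few of their transcripts.

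For fatty acid synthesis 8 of 14 genes fell, with ACSS2 at -0.91 (SE 0.0608), and 4 rose (camera adjusted p = 0.223). Axon guidance and neuronal genes had 6 higher, led by SEMA3A, and 6 lower, led by SYT1 (-1.35, SE 0.0577), of 17. Their median was -0.03, their mean 0.20 and their test pointed up (adjusted p = 0.232). Of 34 nuclear oxidative phosphorylation genes 6 rose and 11 fell, with UQCRC2 at -0.56 (SE 0.0414, camera adjusted p = 0.588). Of the 13 mitochondrially encoded transcripts 3 rose and 6 fell, with COX1 at -0.45 (SE 0.0321, camera adjusted p = 0.392). NRF2 targets had 4 higher, such as GCLM (0.66, SE 0.0475), and 7 lower, such as ABCC2 (-0.87, SE 0.0827), of 17 (camera adjusted p = 0.689). NF-kB targets and inflammatory cytokines had 4 higher, such as TNFAIP2 (0.67, SE 0.0573), and 3 lower, such as ICAM1 (-2.59, SE 0.385), of 14. Their median and mean were -0.04 and -0.01 and the test pointed up (adjusted p = 0.787). Of 5 tested intestinal differentiation genes 3 rose, KRT20, CA2 and HNF4A, and 2 fell, CDX2 and FCGBP (camera adjusted p = 0.787). Without deletion replicate 1 the calls of CA2, CDX2 and FCGBP were lost (edgeR adjusted p = 0.187, 0.18 and 0.167), and without deletion replicate 2 those of KRT20 and FCGBP (0.176 and 0.0849). FCGBP also lost its call without control replicate 2 (0.175), with plain library totals (0.0552) and with DESeq2 (0.0731), and CDX2 with plain library totals (0.0567). CA2 lost its call without control replicate 3 (0.0528), with no filter on low counts (0.0538) and with DESeq2 (0.0579). The call of HNF4A was not followed over the alternatives. In these 7 lists, and in the HOX, ribosome biogenesis, metallothionein and histone lists, the counts adjusted over the list alone were the same. By fry, 27 of the 32 lists moved on balance in one direction, a test that compares no list with other genes.

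Markers of other cell types stayed low. Fewer than 5 members of these lists and of the cancer-testis antigens passed the count filter, so their summed CPM values (counts scaled to the library total) are given with no test. Fibroblast markers summed to 67.3 ± 7.53 in control and 102.6 ± 0.162 in deletion libraries (SD, n = 3 and 2), mostly from FBLN1, which rose (log2 0.68, SE 0.0574). Endothelial markers summed to 12.3 ± 0.987 and 20.9 ± 0.0972, mostly from ESAM, which rose (0.92, SE 0.119). Blood cell markers summed to 13.5 ± 3.72 and 15.1 ± 0.0502, and liver and kidney line markers to 23.1 ± 1.84 and 20.6 ± 0.622. Cancer-testis antigens summed to 257 ± 3.64 and 273 ± 1.051, mostly from MAGEB2.

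Along chromosome 5, 2 stretches of neighbouring genes shifted together, found in a scan chosen after the data were seen. Their borders are those of genes at the centre of passing windows, so they do not mark where a shift starts or ends. From 21882526 to 41921636 on the short arm, 34 of 38 tested genes (89.5%) were higher than the median gene, with a median log2 fold change of 0.53 (median absolute deviation 0.413), and 27 rose and 2 fell by the edgeR test. The smallest p-values of this block were those of the nucleoporin gene NUP155 (log2 0.90), SUB1 (0.72) and SKP2 (0.99), which encodes a ubiquitin ligase subunit that targets CDK inhibitors. Its largest rise was that of the glutamate transporter gene SLC1A3 (log2 4.11, SE 0.403), with 5, 9 and 1 reads in control and 83 and 65 in deletion libraries. From 52787916 to 69920867 on the long arm, 54 of 60 tested genes (90%) were lower, with a median of -0.88 (0.469), and 48 fell and 1, PLK2 (1.095), rose. NLN (-1.75) and ERBIN (-1.104) fell here, as did RAD17 of the DNA damage list. In all 6 pairs of a deletion and a control library the medians were 0.53 to 0.57 and -0.99 to -0.85. The pairs share libraries, and the blocks were chosen on these same libraries. This range therefore shows only that no single library made the shift. The window median that 95% of shuffles of the gene order stayed under was 0.38. The blocks hold 78 of the 7626 called genes with a position.

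**Figure D3:**
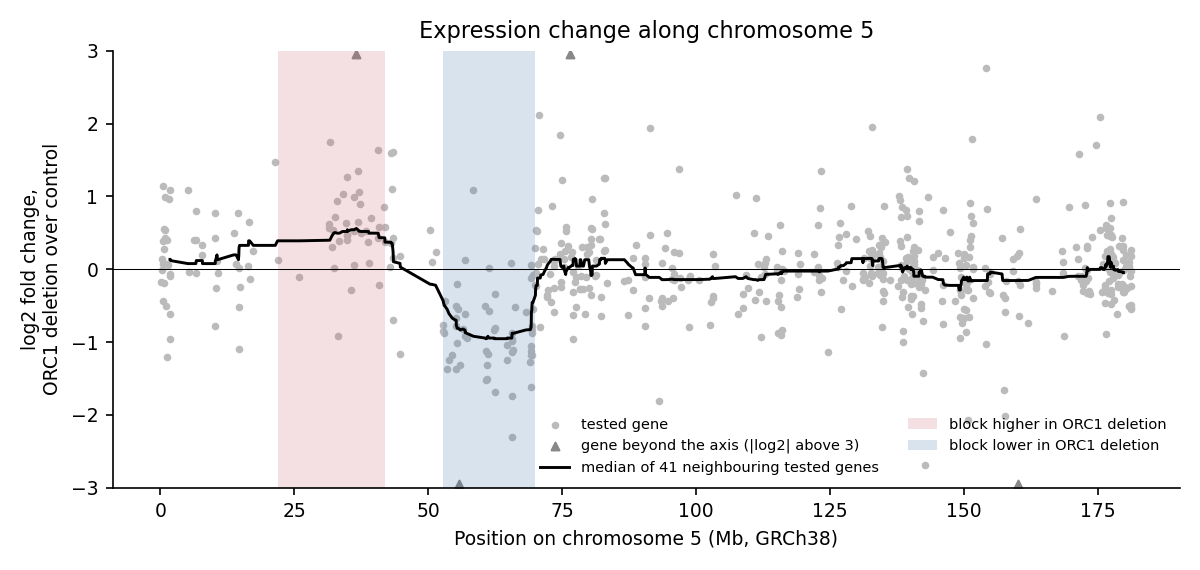
Log2 fold change of deletion over control (y axis) for the 622 tested genes of chromosome 5 by position in megabases on GRCh38 (x axis); the line is the median of 41 neighbouring tested genes, shaded areas are the higher block (red) and the lower block (blue) and triangles are 4 genes beyond the axis. The line reaches above 0.38 in the first block and below -0.38 in the second; outside the blocks it lies between -0.36 (SERF1B) and 0.39 (RETREG1), and windows centred on 2 genes there pass 0.38.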

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

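Of the tests in this part, the one on genomic DNA and the scaling by plain library totals were chosen only after the results were seen; the others were chosen before.

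Reads that HTSeq assigned to no gene were left out of the tests here but kept as a gene in the authors' comparison. They made up 4.672% ± 0.061 (SD, n = 2) of the counts in the deletion libraries and 3.627% ± 0.254 (n = 3) in control. Every deletion library lay above every control library. Without the gene annotation and the strand setting of the counting, these reads cannot be placed outside genes. The share of gene counts in annotated long non-coding RNA genes was 0.948 times that of control, 0.522% against 0.55%. Reads counted in these genes are not among those assigned to no gene. This ratio therefore cannot decide whether more RNA from non-coding loci raised the share assigned to no gene. Genomic DNA in the libraries cannot be told apart from other sources. The 380 olfactory receptor genes below the count filter held 145 reads in control and 86 in deletion libraries. Their ratio scaled to library totals was 1.113 (95% interval 0.842 to 1.463). The interval holds both 1 and the ratio of the shares assigned to no gene, 1.288. Transcripts outside the annotation, such as readthrough or unannotated genes, and a biological effect of the deletion may also raise this share and remain untested.

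Reads that overlap more than 1 gene were 6.423% ± 0.002 (SD, n = 2) of the counts in the deletion libraries and 6.334% ± 0.023 (n = 3) in control.

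The higher ORC1 RNA in cells labelled with an ORC1 deletion may have technical or biological sources. Normalization is argued against, since the log2 fold change was 1.088 with DESeq2 size factors and 1.155 with plain library totals. A gain of the wider region around ORC1 is argued against, since its 20 nearest tested neighbours had a median of -0.143 (median absolute deviation 0.339). A larger share of cells in the G1/S program, when ORC1 is transcribed, remains open as a hypothesis: the 23 licensing and firing factors rose with a median of 0.574 (0.248), but only 2 of them reached the change of ORC1. Feedback on the edited gene, a stabilised edited transcript or a gain of ORC1 alone were not tested.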

How the results depend on the processing

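Plain library totals and the tests without the genes of the chromosome 5 blocks were chosen only after the results were seen. Over the alternatives run, genes that rose numbered 2705 to 4539 and genes that fell 3026 to 4312, and 0 genes called both there and in the reported comparison differed in direction. At a mean normalised count of at least 100, which leaves fewer genes to test, 196 genes were at least 2-fold higher and 225 at least 2-fold lower. With the Benjamini-Yekutieli adjustment, which is stricter by construction, 398 were at least 2-fold higher. Of the lists, 3 were called with an estimated correlation. When ranked by log2 fold change 7 were called (mitosis, licensing and firing, replication fork, DNA damage, interferon-stimulated, ribosomal protein and unfolded protein genes), and the cause was not tested. The estimated correlation of the DNA damage (-0.03), interferon-stimulated (0) and cholesterol (-0.002) lists lay below the preset 0.01. A correlation above the preset is therefore argued against as the reason that these lists lost their call. The other reported lists that lost it had estimates from 0.014 (cohesin) to 0.55 (ribosomal proteins). The licensing and firing list, with an estimate of -0.025, kept its call, but its unadjusted camera p rose from 5.77e-15 to 0.00327. A call lost with an estimated correlation therefore does not by itself show that the genes of a list are correlated. Leaving out 1 library in turn gave 2851 to 3557 genes higher, 3301 to 3769 lower, 456 to 609 at least 2-fold higher, 459 to 489 at least 2-fold lower, 16 to 17 lists and a log2 fold change of ORC1 of 0.96 to 1.19; where a single deletion library was left, it was assumed to vary like the control libraries. The replicate numbers do not pair the libraries (correlations of deviations 0.001 and -0.019). The fit with the replicate number as a block left out control replicate 3, whose number no deletion library holds. It gave 3626 genes higher, 3799 lower, 600 and 486 at least 2-fold higher and lower, 19 lists and ORC1 at 1.14. In that fit camera did not call the mesenchymal list (adjusted p = 0.193). It called the lists of ORC subunits (0.0401), antigen presentation (0.0272) and ribosome biogenesis (0.0401). STAG1 did not pass the edgeR test (adjusted p = 0.0824). Without control replicate 3 and with no block, camera did not call the mesenchymal list (adjusted p = 0.0503) and STAG1 did not pass the edgeR test (0.0922). These 2 changes therefore cannot be credited to the block. Of 135 called named genes 117 kept their call in every alternative that tested them and 18 lost it in at least 1, with 0 reversals; 13 of the 32 lists had no change of call in those that tested them. Without the chromosome 5 blocks 3742 genes were higher and 3883 lower. Alternatives for normalised values only (other pseudocounts, and another adjustment over the authors' p-values) were not run, as the table holds counts. In simulated data at the real depths and numbers of libraries, 52% of the smallest changes tried were recovered; depth was not varied apart from the number of libraries.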

Other observations

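The test of the chromosome 5 blocks was chosen before its result was seen; the lists of genes by shared symbol stem and of genes near absent in 1 group were chosen only after the data were seen.

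Some genes were near absent in 1 group. With under 0.1 CPM (counts scaled to the library total) on average in control and at least 1 in every deletion library were 8 genes, among them APOBEC3G, a cytidine deaminase that restricts retroviruses (0.0733 and 10.2 CPM), AOAH (0.0354 and 4.92), the collagenase gene MMP13 (0.0365 and 2.69) and GLIS3-AS1 (0 counts, which allows up to 0.0558, and 6.29). GLIS3-AS1 runs antisense to GLIS3, which also rose, so its reads are uncertain without the strand setting. In the opposite direction were 6 genes, all protein-coding. DTNA and ZNF566 had 208 and 157 counts over the control libraries and 0 over the deletion libraries, which allows up to 0.105 CPM. PXDN, a peroxidase of the basement membrane, had 4.35 CPM in control and 0.0662 in deletion libraries, and the architectural chromatin gene HMGN5 2.70 and 0.0369. SLC22A17 and SLC5A1 complete this set.

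Genes that share a symbol stem were tested with camera as 166 families of at least 10 tested genes. Of these families, 10 were called with the preset correlation and 0 with an estimated correlation. In the run with an estimated correlation every family had an adjusted p of 0.92 or more. That run therefore told no family apart, and its values are not read as evidence against any shift. Of 45 RPL genes, which encode proteins of the large ribosomal subunit or relatives of them, 43 fell and 1, RPL26L1, rose (median log2 fold change -0.57, adjusted p = 1.51e-49, but adjusted p = 0.925 with an estimated correlation). RPL26L1 did not pass the edgeR test without deletion replicate 2 (adjusted p = 0.0573). Of 41 RPS genes 31 fell and 4 rose (median -0.51, adjusted p = 1.43e-23, but adjusted p = 0.925 with an estimated correlation). Those that rose were RPS10, with 7 to 11 reads in the control libraries and 19 and 21 in the deletion libraries, and the kinase genes RPS6KA5, RPS6KB2 and RPS6KL1, which encode no ribosomal protein. None of the 4 passed without deletion replicate 1 (edgeR adjusted p = 0.101 to 0.172), RPS10 and RPS6KL1 also not without deletion replicate 2 (0.0927 and 0.103), and RPS6KL1 not without control replicate 1 (0.0558). Of 14 PSMD genes, for the regulatory particle of the proteasome, 12 rose and 0 fell (median log2 fold change 0.26, adjusted p = 0.00149, but adjusted p = 0.925 with an estimated correlation), with PSMD2 at 0.57 (SE 0.0296) and PSMD1 at 0.55 (SE 0.0381). Of 11 SRSF splicing factor genes 8 rose and 3 fell (median 0.40, adjusted p = 0.000469, but adjusted p = 0.943 with an estimated correlation), with SRSF1 at 0.96 (SE 0.0361). Of 15 KLF transcription factor genes 10 fell and 1, KLF6, rose (median -0.34, adjusted p = 0.0154, but adjusted p = 0.943 with an estimated correlation), with KLF9 at -1.73 (SE 0.0955) and KLF4 at -1.07 (SE 0.055). Of 19 keratin genes 14 rose and 0 fell (median 0.94, adjusted p = 8.39e-07, but adjusted p = 0.943 with an estimated correlation), with KRT80 at 2.06 (SE 0.0764), though some keratin genes share near-identical sequence.

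A few genes rested on 1 library. Of 10562 tested genes with a mean normalised count of at least 100, 8 differed by more than 4-fold between libraries of 1 group. CD99 had 29 reads in deletion replicate 1 and 645 in deletion replicate 2, and U2AF1L5, a near copy of U2AF1, had 882 reads in control replicate 2 and 63 and 54 in the other control libraries.

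A candidate explanation for the chromosome 5 blocks is a copy-number difference between the deletion cells and the control cells, since the block medians of 0.533 and -0.876 lie near the log2 ratios of 3 against 2 copies (0.585) and of 1 against 2 copies (-1). An earlier test counted the tested genes that shift in their block's direction (89.8%), but the blocks were chosen on these genes, so it was replaced by a test on genes that had no part in finding the blocks: 10 of the 24 genes below the count filter inside the blocks (41.7%, exact 95% interval 22.1 to 63.4) shifted in their block's direction, where a shift by the block medians would give 74.5%. That value met the bound set beforehand as speaking against copy number, and the 74.5% already includes the spread of such genes elsewhere. The 74.5% does not repeat, after the shift, the choice of genes by their reads. Some of the 24, such as RPS4XP6 and GUSBP3, carry symbols of gene copies, whose reads are uncertain here. As a set these 24 genes did not show the shift that the block medians would give, since the interval lies below 74.5%. This result is not read as an exclusion of copy number for the tested genes, a choice made after it was seen. Genes below the filter are near the floor by construction (10 to 34 reads over the libraries, median 13). Copy number and coordinated regulation cannot be told apart here, as DNA content was not analysed.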
